A study of Danio rerio with 8 samples.

How the data were processed

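Whole zebrafish embryos of the WIK strain were measured by HT-SuperSAGE, a method that sequences 1 short tag from the cDNA of a transcript next to a CATG site. Per the labels, polyadenylated RNA was used and several samples shared each lane of an Illumina GA2 flow cell, each with its own barcode. The deposited values are raw counts of each distinct tag sequence in each library, 1 list per library. The lists held whole numbers only, and no normalised value, gene name or summary line was among them. Tags were 22 to 32 bases long and each ended in CATG. How the authors trimmed reads, or whether they removed reads with low base quality, is not given in the sources used here.

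There were 8 libraries, from control embryos and from embryos exposed to silver nanoparticles, bulk silver or silver ions, 24 or 48 hours after fertilisation (hpf), with 1 library per group. Per the labels' protocols, each treatment had 1 glass chamber with 400 mL of water, and 3 pools of 50 embryos were taken from each chamber at each time; how the pools went into the libraries is not given in the sources used here. Both libraries of a treatment came from the same chamber, so a treatment and its chamber cannot be told apart. Their barcodes also ended in the same base: T for control, G for nanoparticles, C for bulk silver and A for ions. A treatment and its last barcode base therefore cannot be told apart either.

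The 8 lists were joined by tag sequence, which gave 606259 distinct tags and 13680994 counts. No transcript sequences were at hand, so no tag was assigned to a gene, and the unit of every comparison was the tag sequence as deposited. Many tags were length variants of each other, with 1 or more bases added at the 5′ end. In alternatives chosen after seeing the data, tags with the same last 22 bases were summed and called a site, which gave 367592 sites. A tag 1 substitution away from a tag at least 50 times as abundant was called an error neighbour; 121978 tags with 4.54% of all counts met this definition.

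Tests across tags used the quasi-likelihood test of edgeR 4.0.16 with limma 3.58.1 in R 4.3.3, with TMM scaling. P-values were two-sided, with Benjamini-Hochberg adjustment within each contrast. A tag was called at an adjusted p of 0.05 or less. The prior count of 2 was used for log2 CPM values and not for the log2 fold changes of the tests. For a tag with few or no counts in a group, the size of that log2 fold change depends on the smaller prior of the fit. The SE printed with a log2 fold change was its absolute value divided by the square root of the test's F statistic. It restates the test and is not a separate standard error of the coefficient. Intervals of log2 fold changes, and their half-widths, were built from this SE. For tags with few or no counts in a group, such an SE does not measure sampling error. The filterByExpr function with a minimum count of 10, grouped by time, kept 9159 tags, which held between 83.8% and 90.2% of the counts of each library. The time comparison set the 4 libraries of 48 hpf against the 4 of 24 hpf. The silver comparison set the 6 exposed libraries against the 2 control libraries with time as a covariate. The last model, with a term for time and a term for treatment, compared each form of silver with control and the forms with each other. In that model the spread was that between times within a treatment, with 3 residual degrees of freedom, and the p-values of all 3 models measure spread between these libraries, not between replicate exposures. The biological coefficient of variation was 0.499 in the time model and 0.452 in the model with treatment terms.

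For each exposed library and the control library of its time, the ratio of scaled CPM (a tag's count relative to its library total) was computed with an exact Clopper-Pearson 95% interval, and a tag was counted as higher or lower when the whole interval lay beyond 1.5-fold. These intervals cover counting error only, since reads of 1 molecule copied in PCR are not independent. Where 1 library held no count of a tag, the ratio was computed against a floor of 3 counts in that library and is given as a lower bound; the floors lay between 1.34 and 2.52 CPM. Correlations between sets of log2 ratios were computed across the 9159 tags, and for forms that share a control library they were set beside 100 simulated sets of libraries with no difference between treatments. The position of a library between the stages was the mean log2 CPM of tags called higher at 48 hpf minus that of tags called lower, with the tags called from the other 3 treatments.

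The rules for naming items were fixed for genes before the data were examined and were applied to tags. For the time comparison the rule named, among called tags that moved the same way in all 4 treatments and had a mean of 20 CPM or more, the 12 with the highest and the 12 with the lowest log2 fold change. For silver and for each form it named up to 10 called tags in each direction at a mean of 20 CPM or more and, where fewer were called, those with the smallest unadjusted p and 1 sign in all exposed libraries. For each pair of libraries it named the 3 tags in each direction whose intervals lay farthest from 1.

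The models were tested on simulated counts drawn from the real means and library sizes of the 9159 tags, with 50 tags changed at each of 4 fold sizes. Their spread was edgeR's trend of dispersion with abundance, from the model with treatment terms. The simulated libraries with no difference between treatments used the same trend and placed more tags past the size rule than the real ones. Recovery in the real data may therefore differ from these shares. The time model recovered 12% of tags changed 2-fold, 54% at 4-fold, 94% at 8-fold and 100% at 16-fold, with 6 false calls. The silver model recovered 10%, 38%, 88% and 98% at the same fold sizes, with 7 false calls. For silver ions against control the shares were 0%, 16%, 52% and 98%, with 4 false calls. In the real data the median half-width of the 95% interval of a log2 fold change, over the 3187 tested tags with a mean of 20 CPM or more, was 0.9 for time, 1.08 for silver and between 1.26 and 1.28 for contrasts of single forms.

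Alternatives were other scaling (size factors of DESeq2 1.42.0, or library totals alone), no filter on low counts, a minimum count of 50, treatment as a block, the DESeq2 Wald test, stricter size rules and leaving out libraries. Alternatives chosen after seeing the data were length variants summed, error neighbours removed, both steps together, and a GC correction, which was a loess curve of each library on the GC content of the tag with a span of 0.5. With library totals in place of TMM the median log2 fold change of all tested tags moved upward. It moved by 0.2 for time, 0.25 for silver, 0.4 for nanoparticles, 0.18 for bulk silver and 0.13 for ions. Log2 fold changes of the models and ratios of library pairs are given relative to TMM. Printed CPM values, and multiples of the floor in the time comparison, used library totals, so these multiples stand higher than TMM would give. Lists of genes for tissues and stress responses, and genes named in advance, were fixed but not analysed here, because tags were not assigned to genes; the alternatives for assigning tags to genes were not run for the same reason. Counting and checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.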

Results

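Tags of transcripts were counted in 8 libraries of whole zebrafish embryos, 1 library for each of 4 treatments at each of 2 times. The treatments were water alone (control), 10 nm silver nanoparticles at 5 µg/L, bulk silver particles at 5 µg/L and silver ions, given as silver nitrate at 0.25 µg/L. Embryos were collected at 24 and 48 hpf. Library depth ran from 1189323 counts (nanoparticles, 48 hpf) to 2238816 counts (nanoparticles, 24 hpf). Of 606259 distinct tags, 401226 (66.2%) were seen once, and 9159 tags were tested. There was no replicate check within a group, intervals of ratios and shares cover counting error only, and p-values measure spread between these libraries.

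The libraries parted first by time. The first principal component of the tested tags held 42% of the variance and the second 25.3%, and the silver ion library of 24 hpf stood farthest from the rest, at −107 on the first and 76.2 on the second component. Across tags, which are not independent replicates, the median correlation of log2 CPM was 0.831 between libraries of the same time and 0.685 between libraries of different times. The silver ion library of 24 hpf had a median correlation of 0.698 with the other libraries of its time.

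**Figure D1:**
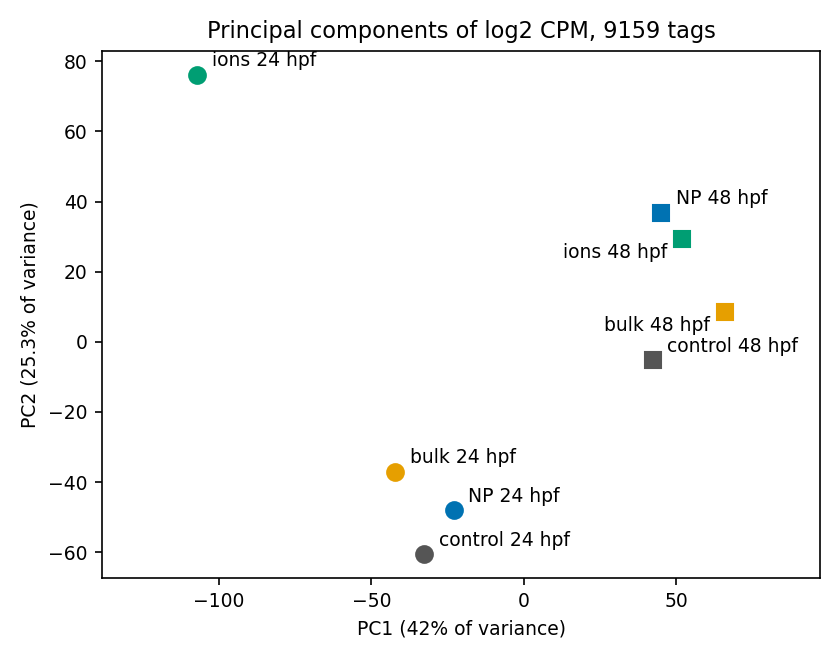
Positions of the 8 libraries on the first and second principal components of log2 CPM of the 9159 tested tags, with axes in component scores and the percent of variance on each axis. The silver ion library of 24 hpf lies apart from the other 3 libraries of its time.

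GC content and the first bases of a tag also separated libraries. Across the 8472 tested tags that were not error neighbours, the correlation of GC content with a tag's deviation from the mean of its time was 0.775 in the silver ion library of 24 hpf, −0.518, −0.599 and −0.2 in the control, nanoparticle and bulk silver libraries of that time, and between −0.216 and 0.117 in the 4 libraries of 48 hpf. The mean of a time includes each of its 4 libraries, so a trend in 1 library moves the other 3 the opposite way. In the nanoparticle library of 48 hpf, the 172 tags beginning with TTG that were neither error neighbours nor tags of the dominant sites had a median log2 ratio to control of −2.78 and the 137 such tags beginning with TAG a median of −1.91, while the median over 61 classes of first 3 bases was 0.2. Against the same control library, the TTG and TAG medians were −1.11 and −1.05 with bulk silver and −0.37 and −0.31 with ions. At 40 sites that had a tag beginning with TTG and a length variant with another first base, the TTG tag was lower than its length variants in 40 of 40, by a median log2 difference of −3.39 after subtraction of the control library. Within single libraries the median log2 ratio of the TTG tag to its length variants at these sites was −2.41 with nanoparticles at 48 hpf, 0.2 with bulk silver, 0.99 with ions and 1.48 in control at that time, and between 0.7 and 1.28 at 24 hpf. These classes were examined after the values had been seen.

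**Figure D2:**
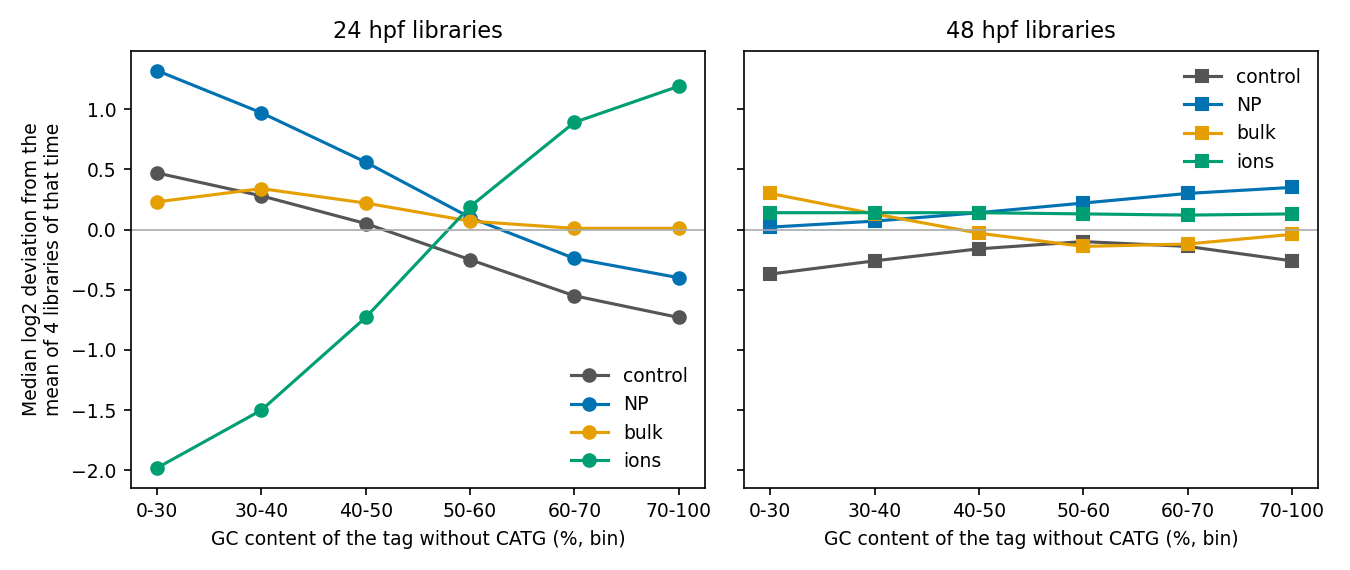
Median log2 deviation of the 8472 tested tags that were not error neighbours from the mean of the 4 libraries of their time, against bins of GC content of the tag, with 1 line per library and 1 panel per time. In the silver ion library of 24 hpf the median runs from −1.98 in the lowest GC bin to 1.19 in the highest.

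Embryos at 48 hpf were compared with embryos at 24 hpf to describe the change with developmental stage that all treatments shared. Most of the named tags that rose with time shared a common end. TAAAACACTAGTACCAGGAGTCCATG rose by a log2 fold change of 8.47 (SE 0.79) from 4 counts in all libraries of 24 hpf together to 279.5 ± 107 CPM (SD, n = 4) at 48 hpf. TTGAAACACTAGTACCAAGAGTCCATG had no count at 24 hpf and 264 ± 151 CPM (SD, n = 4) at 48 hpf. On library totals without TMM, this was 138-fold above a floor of 3 counts per library at 24 hpf. TAGGGACACTAGTACCAGGAGTCCATG was 114-fold above that floor in the same way and on the same scale, and CAGATCATTAGTACCAAGAGTCCATG 71-fold. Without that end, TCTGCTAAACTCTGCTCCAGACTCATG was 44.3-fold and TGCAACAGGCTTTCCCCCAAAGCATG 24.1-fold above the same floor at 48 hpf, also on library totals.

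Tags that fell with time included a set of length variants of 1 abundant site. The most abundant of the named tags was TTGGAGCCCAGCAGGGCCTGCAGCATG, which went from 3291 ± 2331 CPM at 24 hpf to 115 ± 88.1 CPM at 48 hpf (SD, n = 4 each) and fell by 5.12 on the log2 scale (SE 0.85). Its length variants TTTGGAGCCCAGCAGGGCCTGCAGCATG and TGGAGCCCAGCAGGGCCTGCAGCATG fell by 4.35 and 4.29. TGTGGTGGGGGGAACACACTGTACATG fell from 47.4 to 1.76 CPM, CATTAAAACGGGGGTCATAGCGGCATG fell by 4.49 on the log2 scale, and ACGTAAAAGCAACATACAGAACACATG fell by 4.28. ACCTGGAACTGGTAGCCAGATAGCATG went from 370.1 ± 85.3 to 46.6 ± 12.4 CPM and fell by 3.18 (SE 0.3).

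By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 829 tags were higher and 258 lower at 48 hpf, and the smallest adjusted p was 6.74e-05. Of the higher tags, 594 (71.7%) differed by more than 4-fold, as did 115 (44.6%) of the lower ones. Over all 9159 tested tags, called or not, CPM on library totals without TMM was compared between times. The 4 libraries of 48 hpf lay wholly above those of 24 hpf in 1435 tags and wholly below in 329. Together these were 19.3%, where chance gives 2.86% if the libraries are taken as unpaired. Both libraries of a treatment came from the same chamber, which that share ignores, so the comparison does not exclude chance. Library totals moved the median log2 fold change for time by 0.2, which favours the first of these counts. With treatment as a block the counts were 674 higher and 212 lower. They were 896 and 168 with library totals alone and 1072 and 652 with DESeq2. With the GC correction, chosen after seeing the data, they were 1058 and 567. The count fell to 395 (343 higher, 52 lower) without both bulk silver libraries and to 545 (453 higher, 92 lower) without both control libraries; without the silver ion library of 24 hpf alone it was 1466, with 439 lower. A total of 419 pairs of length variants had a correlation of 0.944 in their log2 fold changes with time across pairs, which are not independent replicates, and of the 74 pairs with either tag called, 57 had both called and 0 had opposite signs.

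A family of tags with a shared end made up 10 of the 12 named tags that rose. Its members ended in TAGTACCA, then A or G, GAGT, C or G and CATG, a stretch chosen after the values had been seen. All 26 tested members that were not error neighbours, from 12 sites, were called higher at 48 hpf by edgeR. Their log2 fold changes lay between 5.33 and 11.77, with a median of 8.23. Of the 8446 other tested tags that were not error neighbours, 9.2% were called higher. Read on the opposite strand from the ATG of the CATG site, 21 of the 26 gave MDSWY and 5 gave MHSWY, each followed by a stop codon. Summed over the family, the 24 hpf libraries held 3.6 ± 2.6 CPM and the 48 hpf libraries 2533 ± 817 CPM (SD, n = 4 each); no test of this sum is given, since the stretch was taken from tags that had been called higher. The 48 hpf values were 2636 CPM in control, 1375 CPM with nanoparticles, 3279 CPM with bulk silver and 2841 CPM with silver ions. All 26 were also called with size factors of DESeq2, with library totals alone and after the GC correction. At a minimum count of 50 only 10 were tested, and all 10 were called higher. Several members began with TTG or TAG, the first bases that were low in the nanoparticle library of 48 hpf.

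**Figure D3:**
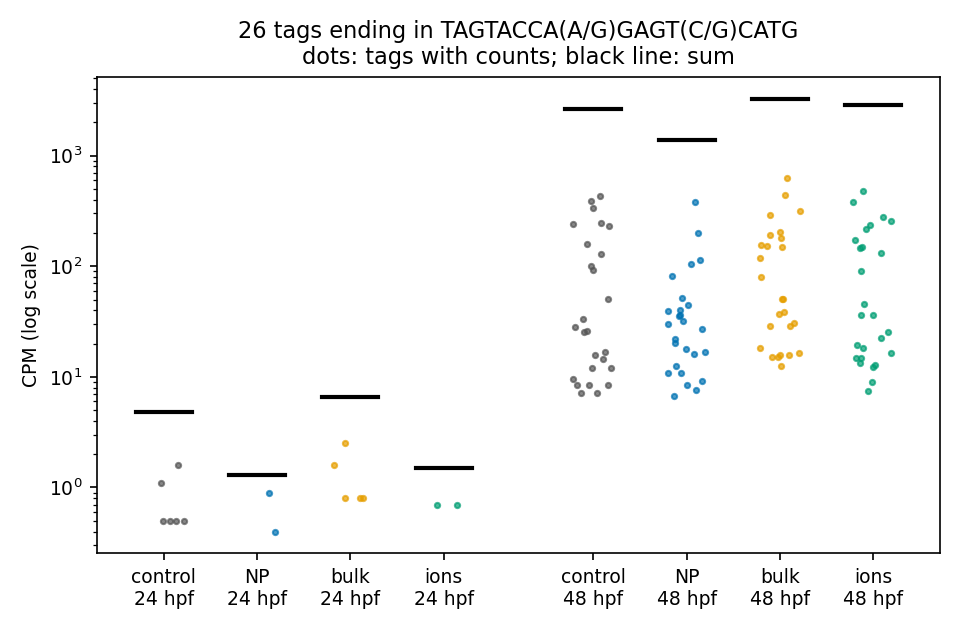
CPM on a log axis of the 26 tested tags of the family with the shared end, error neighbours left out, in each of the 8 libraries. Dots are tags with at least 1 count and the black line is the family's sum. The sum lies between 1.3 and 6.6 CPM in the 24 hpf libraries and between 1375 and 3279 CPM in the 48 hpf libraries.

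A single pair of sites dominated the libraries; their tags were not assigned to a gene or a class of RNA, so it is open whether they come from messenger RNA or from ribosomal or other RNA carried into the libraries. The tags CCGGCCGTGTGCACTTAGACTTGCATG and CCGGCCGTGTGCACTTAGACCTGCATG differed by the substitution T21C, with positions counted from 1 at the 5′ end of the first tag. Both sites together held 33.2% of the counts in control, 15.197% with nanoparticles, 16.5% with bulk silver and 1.07% with silver ions at 24 hpf, and 14.5%, 1.62%, 16% and 0.784% in the same order at 48 hpf. The second site's share of the pair was 35.5%, 30.7%, 38.8% and 47.1% in control, nanoparticle, bulk and ion libraries at 24 hpf, and 63.3%, 62.1%, 65.5% and 56.5% at 48 hpf. Clopper-Pearson 95% intervals were widest in the ion libraries, at 46.3% to 47.9% and 55.8% to 57.3%. The mean share was 38 ± 6.9% at 24 hpf and 61.9 ± 3.82% at 48 hpf (SD, n = 4 each). Both libraries of a treatment came from 1 chamber, and within treatments the share was higher at 48 hpf in 4 of 4, by 23.8 ± 9.82 percentage points (SD, n = 4; exact paired permutation test, two-sided p = 0.125, the smallest that 4 pairs allow). Taken as 4 against 4 unpaired libraries, the exact permutation test gave p = 0.0286, the smallest it allows. Without the ion libraries the means were 35% and 63.6%.

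**Figure D4:**
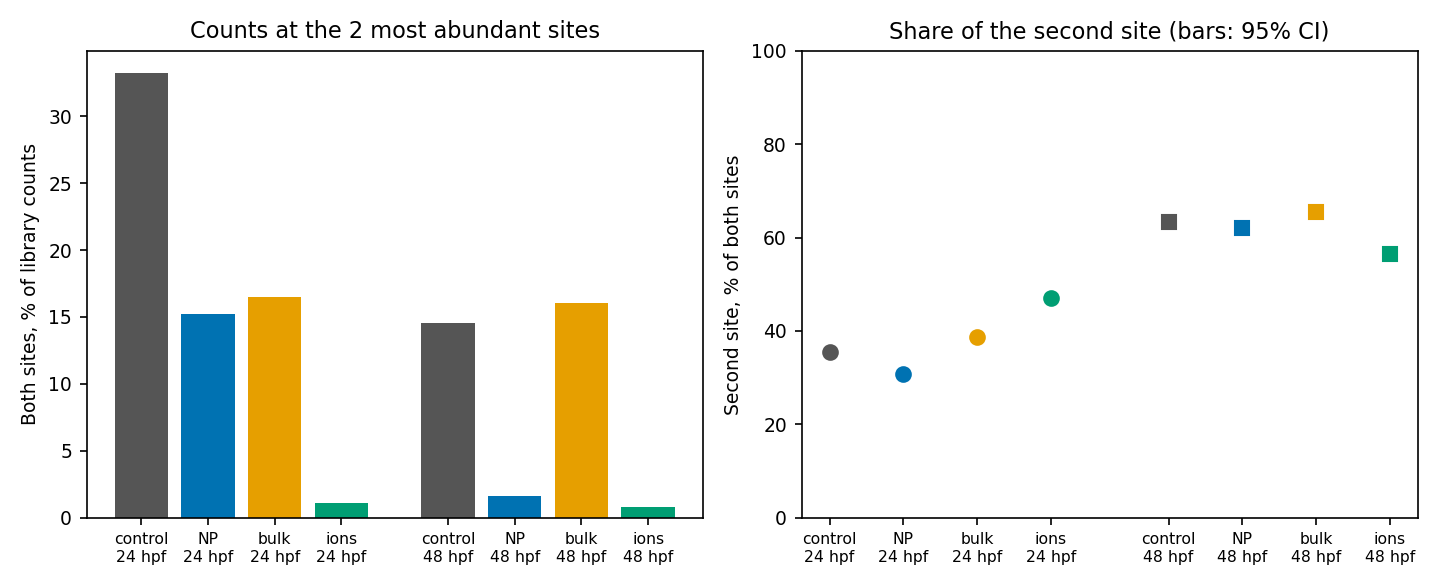
Percent of all counts held by both dominant sites together in each library (bars), and the second site's percent of the pair with exact 95% intervals, which are smaller than the markers (points). The second site's share lies between 30.7% and 47.1% at 24 hpf and between 56.5% and 65.5% at 48 hpf.

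Exposure to any form of silver was compared with control to look for a response common to the forms. GACGGCTCGGATACTCTTCCCAGCATG had no count in either control library and 51, 3 and 78 counts with nanoparticles, bulk silver and ions at 24 hpf, then 127, 30 and 77 counts at 48 hpf. GACGGATGTGCTGGGACGTCCGGCATG had 197 counts in control and 841, 507 and 1873 in the exposed libraries at 24 hpf, and 335 against 937, 1001 and 1165 at 48 hpf, a log2 fold change of 1.95 (SE 0.74). ATCTCGATATGGCAGGGGGGGGTCATG had a log2 fold change of 1.2 (SE 0.44). Tags with the smallest unadjusted p were lower: CCGGGCGTGTGCACTTAGACTTGCATG had a log2 fold change of −2.25 (SE 0.41, unadjusted p = 0.000334 by edgeR) and CCGACCGTGTGCACTTAGACTTGCATG of −2.57 (SE 0.49, unadjusted p = 0.000433 by edgeR), and all 10 lower tags that the rule names were error neighbours, 9 of them of the dominant tags. The rule took tags with 1 sign in all exposed libraries, so that a sign shared by the forms comes from the choice. None of these tags passed the test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 tags were called, with 236 (2.58%) at an unadjusted p under 0.05, and DESeq2 called 2. The count was 16, all lower, without the bulk silver library of 24 hpf and 400 (25 higher, 375 lower) with no filter on low counts. A term for a difference in the silver effect between times gave 0 calls by edgeR, with 72 tags (0.79%) at an unadjusted p under 0.05; that term was fitted with edgeR only.

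Each form of silver was then compared with control over both times, to set apart the forms. With silver ions both dominant tags were lower: CCGGCCGTGTGCACTTAGACTTGCATG fell by 9.51 on the log2 scale (SE 1.22) and CCGGCCGTGTGCACTTAGACCTGCATG fell by 9.74 (SE 1.19), each with an adjusted p of 0.0249 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Other called tags included CTGGCCGTGTGCACTTAGACTTGCATG, with 1616 counts in control and 0 with ions at 24 hpf, and CCGGCCGTTTGCACTTAGACTTGCATG, with 2495 and 0. All 35 tags called lower with ions were dominant tags or neighbours of them by 1 substitution, 33 of them neighbours, and edgeR called 0 tags higher while DESeq2 called 14 higher. Summed over length variants, the first site had a log2 fold change of −4.47 (95% interval −6.56 to −2.39, adjusted p = 0.143 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and the second −4.35 (−6.29 to −2.41, adjusted p = 0.137 by the same edgeR test). With error neighbours removed, 0 tags were called by edgeR, with 341 at an unadjusted p under 0.05; both dominant tags were then at −9.46 and −9.69 on the log2 scale (adjusted p = 0.0741 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The ion count was 0 without either ion library or without the control library of 48 hpf, 10 without the control library of 24 hpf, and 81, 72, 70 and 80 without the nanoparticle or bulk library of 24 hpf or that of 48 hpf in turn. Leaving out an ion or control library leaves that arm with 1 library, which is then assumed to vary like the other treatments. At an unadjusted p under 0.05 there were 465 tags, 3007 without the ion library of 48 hpf and 238 and 274 without the control library of 24 and of 48 hpf, and DESeq2 called 137 in all.

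With nanoparticles 2 tags were called, both lower than control. TTGCCGTTGTACACGCCGACCATG had 152 counts in control and 1 with nanoparticles at 24 hpf, and 146 and 0 at 48 hpf, and fell by 8.53 on the log2 scale (SE 0.86). TTGCGGGTACAGCATTCTGACCCCCATG had 348 and 4 counts at 24 hpf and 306 and 1 at 48 hpf, and fell by 7.69 (SE 0.76). Each had an adjusted p of 0.0358 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 580 tags at an unadjusted p under 0.05. Both begin with TTG, and their sites summed over length variants had log2 fold changes of 0.07 and 0.08. With length variants summed, or with library totals alone, 0 tags were called by edgeR, with 373 and 536 at an unadjusted p under 0.05. The GC correction gave 22 calls (20 lower), and length variants summed with error neighbours removed and the GC correction gave 41 (38 lower), both chosen after seeing the data. The count was 0 without any one of the control, nanoparticle or ion libraries of either time, 10 without the bulk library of 24 hpf and 20 without that of 48 hpf; DESeq2 called 173.

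With bulk silver 0 tags were called by edgeR, with 113 (1.23%) at an unadjusted p under 0.05 and 0 by DESeq2. The tag TTTCGTCTGGCCTCTTCGTGGTCCATG had 8 counts in control and 231 with bulk silver at 24 hpf and 8 and 187 at 48 hpf. Its length variant TTCGTCTGGCCTCTTCGTGGTCCATG had 7 and 135, then 4 and 75. Neither passed the test (adjusted p = 0.999 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). High counts of these tags were not particular to bulk silver. With ions at 24 hpf they had 330 and 215 counts, and with nanoparticles at 48 hpf 101 and 54. Nanoparticles at 24 hpf gave 9 and 7 counts and ions at 48 hpf 10 and 5. Between nanoparticles and bulk silver 0 tags were called by edgeR, with 421 at an unadjusted p under 0.05 and 122 by DESeq2; the edgeR count was 12 without the bulk library of 48 hpf. Between nanoparticles and ions, TTGCCGTTGTACACGCCGACCATG and TTGCGGGTACAGCATTCTGACCCCCATG were lower with nanoparticles, by log2 fold changes of −8.75 and −7.56 (adjusted p = 0.0327 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Summed over length variants their sites were at −1.23 and −0.68 (adjusted p = 0.613 and 0.662 by the same edgeR test), and 0 tags were called with length variants summed or with library totals alone (647 and 697 at an unadjusted p under 0.05; DESeq2 called 178). The count was also 0 without any one of the control, nanoparticle or ion libraries except the nanoparticle library of 48 hpf, without which it was 7, all higher with nanoparticles; it was 5 without the bulk library of 48 hpf, 2 higher and 3 lower. Between bulk silver and ions DESeq2 called 95 tags. By edgeR 0 were called with length variants summed or with error neighbours removed (349 and 284 at an unadjusted p under 0.05). In the main edgeR fit 4 neighbours of the dominant tags were higher with bulk silver than with ions, such as CCGGCCGTGTGCCCTTAGACCTGCATG with a log2 fold change of 9.32 (SE 0.83). That count was 0 without any one control or ion library, and 33, 35, 20 and 9 without the nanoparticle or bulk library of 24 hpf or that of 48 hpf in turn. In contrasts of single forms the median 95% half-width was between 1.26 and 1.28 on the log2 scale, and in simulated data the contrast of ions with control recovered 0% of tags changed 2-fold, 16% at 4-fold and 52% at 8-fold. Recovery in the real data may differ, since the simulated spread came from edgeR's trend of dispersion.

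Single pairs of libraries were compared to describe each form at each time. At 24 hpf TGGGCACTGGGGGGCCCTGTGGCATG had 4 counts in control, 937 with nanoparticles (138-fold, 95% interval 53.7 to 507) and 993 with ions (358-fold, 139 to 1320); it lies 1 substitution from TGGGCACTGGGGTGCCCTGTGGCATG, which had 12134 counts in that control library. AAGCCCCTCACACACACACACACCATG was at least 24.3-fold higher with nanoparticles at 24 hpf, against a floor of 3 counts. TTGGCAGCGATGACCTGCACCTTCATG had 13011 counts in control and 1 with ions at 24 hpf (9030-fold lower, 1620 to 357000), and its whole site was at a ratio of 0.0183. With bulk silver at 24 hpf CGCTCTGCGGATCGGGACTGGCACATG had 1 count against 82 in control (64.2-fold lower, 11.2 to 2570); it lies 1 substitution from CGCTCTGCGGATCGGGACTGGCGCATG, which had 1329 counts with bulk silver and 1477 in control. Several other tags with extreme ratios were length variants of dominant sites, such as CGGCCGTGTGCACTTAGACCTGCATG with 6 counts in control and 5277 with bulk silver, while its site was at a ratio of 0.467.

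At 48 hpf GACGGCTCGGATACTCTTCCCAGCATG was at least 48.7-fold higher with nanoparticles and at least 17.8-fold higher with ions. TCTGGCGATGGACTTGCGGACAACATG was at least 37.8-fold higher with bulk silver and at least 29.6-fold higher with ions, and in both cases its whole site was also without counts in control. TGGCAGCCTGGCCACAGTAACGTCATG had 19287 counts in control and 1 with nanoparticles (17000-fold lower, 3050 to 672000), and its site was at a ratio of 0.109. ATCTCGATATGGCAAGGGGAGCTCATG had 262 counts in control and 2 with bulk silver (180-fold lower, 49.4 to 1500).

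By the rule of size, 210 tags were higher and 551 lower with nanoparticles at 24 hpf, 182 and 198 with bulk silver, and 1392 and 1413 with ions. At 48 hpf there were 207 higher and 914 lower tags with nanoparticles, 144 and 528 with bulk silver, and 102 and 496 with ions. Tags beginning with TTG made up 153 (16.7%) of the 914 lower tags with nanoparticles at 48 hpf and 85 (16.1%) of the 528 lower tags with bulk silver at that time, against 190 (2.1%) of the tested tags. Tags beginning with CCG, 214 (2.3%) of the tested tags and 149 of them tags of the dominant sites or error neighbours, made up 20.1%, 35.9% and 8.1% of the lower tags with nanoparticles, bulk silver and ions at 24 hpf and 11.5%, 13.4% and 25.8% at 48 hpf. Counted as sites with error neighbours removed, the totals over both directions were 296, 184 and 2028 for nanoparticles, bulk silver and ions at 24 hpf and 486, 242 and 221 at 48 hpf, of 7497 sites. The ion total at 24 hpf was 2805 tags and 966 after the GC correction.

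The log2 ratios of a form to control at 24 hpf were compared with those at 48 hpf, which share no library, to see whether a form's difference recurred. Across the 9159 tags, which are not independent replicates, Pearson's r was 0.501 (Spearman's rho 0.29) for nanoparticles, −0.03 (−0.008) for bulk silver and 0.259 (0.003) for ions. Counted as sites with error neighbours removed, r was 0.303, −0.005 and −0.06. With nanoparticles 369 tags were lower at both times, where n1 × n2 / N gives 55, and 58 were higher at both, where it gives 4.7. With ions 217 were lower at both times against 76.5, and with bulk silver 59 against 11.4, beside 57 that went opposite ways against 13.6. Opposite ways numbered 23 against 33.4 with nanoparticles and 75 against 91.1 with ions. The product n1 × n2 / N takes every tag as equally able to pass the size rule. Abundant tags have narrower intervals and pass it more easily, so an excess over that product does not by itself show recurrence. Across treatments, nanoparticles at 24 hpf had an r of 0.369 with ions at 48 hpf, and ions at 24 hpf an r of 0.253 with nanoparticles at 48 hpf; as sites these were 0.093 and 0.043.

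Forms were compared with each other within a time, where they share 1 control library. At 24 hpf, bulk silver and ions had the highest correlation, 0.47 against 0.474 in simulated libraries with no difference between treatments, with a covariance of 0.593 against 0.489. Nanoparticles had an r of 0.281 with bulk silver (simulated 0.503) and 0.207 with ions (simulated 0.499), with covariances of 0.199 and 0.31 against 0.489 and 0.49. At 48 hpf, r was 0.507 for nanoparticles and bulk silver (simulated 0.505), 0.481 for nanoparticles and ions (simulated 0.505) and 0.591 for bulk silver and ions (simulated 0.519). The 48 hpf covariances were 0.514, 0.525 and 0.47 against 0.492, 0.491 and 0.491. Lower tags shared by nanoparticles and bulk silver at 48 hpf numbered 373, against 230 simulated and 52.7 from n1 × n2 / N. Nanoparticles and ions shared 292 lower tags at that time against 232 and 49.5, and bulk silver and ions 279 against 259.5 and 28.6. Higher tags shared at 48 hpf numbered 37, 33 and 42 for the same pairs of forms, against 256, 257 and 274 simulated and 3.3, 2.3 and 1.6 from n1 × n2 / N. At 24 hpf, shared lower tags numbered 111 for nanoparticles and bulk silver (219 simulated, 11.9 from n1 × n2 / N), 225 for nanoparticles and ions (211, 85) and 131 for bulk silver and ions (179, 30.5), and shared higher tags 41 (248, 4.2), 71 (244, 31.9) and 118 (222, 27.7). Each simulated overlap of higher tags at 48 hpf was larger than any form's whole list of higher tags at that time (207, 144 and 102). The simulation thus placed more tags past the size rule than the real libraries held. Its overlaps are therefore no baseline, its spread also enters the simulated r and covariance, and no excess or deficit is read from them. Part of any excess over n1 × n2 / N may come from the shared control libraries, and part from abundant tags, which pass the size rule more easily.

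The position of exposed embryos between the stages was read from tags called with time in the other 3 treatments. Those treatments included both control libraries and not the libraries scored. Selection alone therefore tends to widen the control distance. It tends to move scored libraries of 24 hpf toward 48 hpf and those of 48 hpf toward 24 hpf. As a share of the distance between the control libraries, exposed libraries of 24 hpf lay 0.033 (nanoparticles), 0.017 (bulk silver) and 0.042 (ions) beyond the control library of their time in the direction of 48 hpf. The sign turned for each form in 1 alternative or more, to −0.017 for nanoparticles with the GC correction, −0.012 for bulk silver with library totals alone and −0.032 for ions at a minimum count of 50. At 48 hpf the values were −0.103 for nanoparticles, 0.078 for bulk silver and −0.007 for ions, the last of which was 0.032 at a minimum count of 50 and 0.022 with library totals alone. The nanoparticle value was −0.034 at a minimum count of 50 and −0.064 with library totals alone, and the bulk silver value 0.024 with the GC correction. With tags called from the other 2 silver forms, and so without the control libraries, the values were 0.174 and 0.067 for nanoparticles and 0.299 and 0.163 for ions at 24 and 48 hpf. For bulk silver that selection held no tags and gave no value. With 1 library per group these are values without a test.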

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

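The weighed tests on length variants, on the tags lower with silver ions and on the second dominant site were all chosen after the results they bear on had been seen, while the rule that picks out a library far from the rest was fixed before the data were examined.

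The tag TTGGAGCCCAGCAGGGCCTGCAGCATG had 6763 CPM in the silver ion library of 24 hpf, far from the other 3 libraries of that time, which lay between 1832 and 2492 CPM. The gap was 0.866 of the range of the 4 values. This tag falls in the bin of 60 to 70% GC, where tags of the silver ion library of 24 hpf had a median log2 deviation of 0.89. The medians of that bin were −0.55 in control, −0.24 with nanoparticles and 0.01 with bulk silver at 24 hpf. The GC trend of the library thus goes the same way as the gap, and its part in the gap was not tested. Among 50 groups of 4 libraries examined in this way 1 stood out, where chance gives about 2.5.

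Length variants of the same site, defined as tags with the same last 22 bases, gave different log2 ratios to control; tags were not assigned to transcripts, so an origin in related transcripts was not tested. Counting noise alone is argued against, since the spread between 420 pairs of length variants was at least 2.8 times that from counting in each of the 6 pairs of libraries. A candidate explanation, strongest in the nanoparticle library of 48 hpf, is a loss of tags by their first bases: tags beginning with TTG lay below other length variants of their site by a median log2 difference of −3.39 (quartiles −4.73 and −2.73) at 40 of 40 sites, against −1.21 with bulk silver (33 of 40) and −0.59 with ions (28 of 40) over the same control library, and within that library alone the ratio was −2.41 against 0.2 to 1.48 in the other 7, so the shared control is argued against as the whole source. A step of library making shared by both libraries of a treatment remains open. Such a step cannot be told apart from the treatment's chamber or from the last base of its barcodes. The mean correlation of length-variant differences was 0.578 for libraries of 1 treatment, against at most 0.534 in the other 23 of 24 pairings of the libraries. Bulk silver at 24 hpf was closer to ions at 48 hpf (0.537) than to bulk silver at 48 hpf (0.309). No biological explanation was tested, and the fits that sum length variants bear on this pattern: both tags called lower with nanoparticles were at 0.07 and 0.08 on the log2 scale as sites.

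Tags called lower with silver ions were dominant tags and their neighbours by 1 substitution. The 33 called neighbours may be sequencing errors of the dominant tags, as their median log2 fold change differed from that of the parent tag by 0.37; but 14 of 33 lay within 2 log2 units of the parent and differences ran from −4.38 to 6.12, and the ion libraries held 40 neighbour counts against 17.3 expected at 24 hpf and 92 against 29.6 at 48 hpf, 2.81 times the expected number. GC content as the whole cause is argued against, since all 35 calls stayed called after the GC correction. A shift of reads between tag lengths is argued against as the whole cause, since the site nearest to 0 was still at −4.35 (−6.29 to −2.41) when summed over lengths, but it accounts for part: the tag of 27 bases of that site was at −9.74 (SE 1.19), and the call ended with the smaller fold (adjusted p of 0.137 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A difference in how much of this abundant RNA entered each library, and an effect of silver ions, both remain open, and each treatment had 1 chamber.

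The second dominant site held a larger share of the pair at 48 hpf than at 24 hpf in each of 4 treatments. Sequencing errors of the first site are argued against: the highest share of any other single substitution in a library was 18.87%, below the lowest share of the second site, 30.74%. Tag length is argued against, since the libraries of 48 hpf lay above those of 24 hpf at 4 of 4 lengths from 25 to 28 bases. GC content is argued against as the whole source of the rise. The 48 hpf library had the higher mean GC content in 5 of 16 pairs of libraries but the higher share in 16 of 16. Mean GC content also depends on which RNA a library holds. Within 24 hpf the share did rise with mean GC content, from nanoparticles (52.26% GC) through control (53.85%) and bulk silver (55.49%) to ions (59.88%). At 48 hpf bulk silver had the lowest mean GC content (52.75%) and the highest share. A part of GC content in the shares within a time was not tested. A change of the embryos' RNA with stage stays among the open explanations and is a hypothesis, since the pattern was found and tested on the same data.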

How the results depend on the processing

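Summing length variants, removing error neighbours, the GC correction, their combinations, the stage position from tags of the other 2 forms, leaving out the silver ion library of 24 hpf alone and leaving out libraries in the comparisons of single forms were chosen after seeing the data. Of 263 alternative values for the main results, 149 stayed within the spread or within 1.5 times the count and 114 moved; the cause was not tested except that a minimum count of 50 tests fewer tags and removing error neighbours takes out most tags called with ions. Among 42 called tags that are named, 402 alternatives for the 24 of the time comparison gave 2 that lost the call and 0 that reversed, and 306 for the other 18 gave 99 and 6. The 6 reversals were the sites of both tags called with nanoparticles: TTGCCGTTGTACACGCCGACCATG was at 0.07, 0.04 and 0.05 and TTGCGGGTACAGCATTCTGACCCCCATG at 0.08, 0.05 and 0.12 with length variants summed, also without error neighbours, and also with the GC correction. Tags higher at 48 hpf numbered 296 at a minimum count of 50 and tags lower 125, and lower tags numbered 168 with library totals alone, 400 with length variants summed and error neighbours removed, 567 with the GC correction, 767 with all 3 steps, 652 with DESeq2 and 439 without the silver ion library of 24 hpf. Leaving out the pair of libraries of 1 treatment gave 343 to 892 higher and 52 to 270 lower tags; without the silver ion library of 24 hpf alone there were 1027 higher. Silver calls numbered 400 with no filter, 2 with DESeq2 and 0 to 16 with 1 library left out. For nanoparticles, bulk silver and ions against control, no filter gave 320, 18 and 289 calls, and with 1 library left out, where a lone library is assumed to vary like the other groups, there were 0 to 20, 0 and 0 to 81. Nanoparticle calls against control were 0 with library totals alone, with length variants summed and with error neighbours also removed, 9 with error neighbours removed alone, 22 with the GC correction, 41 with all 3 steps and 173 with DESeq2. Ion calls against control were 18 with library totals alone, 18 at a minimum count of 50, 16 with length variants summed, 0 with error neighbours removed, 0 with both steps, 57 with the GC correction, 3 with all 3 steps and 137 with DESeq2. Nanoparticles against bulk silver gave 130 calls with no filter, 10 with error neighbours removed, 5 with the GC correction, 38 with all 3 steps, 122 with DESeq2 and 0 to 12 with 1 library left out. Nanoparticles against ions gave 0 with library totals alone, with length variants summed and with both steps, 137 with no filter, 15 with error neighbours removed, 14 with the GC correction, 14 with all 3 steps, 178 with DESeq2 and 0 to 7 with 1 library left out. Bulk silver against ions gave 142 with no filter, 8 at a minimum count of 50, 0 with length variants summed, with error neighbours removed, with both steps and with all 3 steps, 95 with DESeq2 and 0 to 35 with 1 library left out. With intervals beyond 2-fold the pair totals were 470 (nanoparticles), 180 (bulk silver) and 1739 (ions) at 24 hpf and 409 (bulk silver) and 385 (ions) at 48 hpf; as sites without error neighbours they were 296 and 184 for nanoparticles and bulk silver at 24 hpf and 486, 242 and 221 for the 3 forms at 48 hpf, and the ion total at 24 hpf was 966 with the GC correction. As sites without error neighbours the correlation between times for ions was −0.06, and correlations between forms were 0.005 for nanoparticles and ions at 24 hpf, 0.419 for nanoparticles and bulk silver and 0.391 for nanoparticles and ions at 48 hpf. The stage position of nanoparticles at 24 hpf was 0 at a minimum count of 50, 0.013 with library totals alone, 0.051 as sites without error neighbours, −0.017 with the GC correction and 0.174 from tags of the other 2 forms; that of bulk silver was 0.003, −0.012, 0.032 and 0.069 under the first 4 of these. For ions at 24 hpf it was −0.032 at a minimum count of 50, 0.079 with the GC correction and 0.299 from tags of the other 2 forms, which also gave 0.067 for nanoparticles and 0.163 for ions at 48 hpf. Rules for assigning tags to genes and tests of gene lists were not run, a minimum of 2 counts per tag left out no tested tag, and the stage position of bulk silver from tags of the other 2 forms gave no value.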

Other observations

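The test over other splits of the libraries and the test on barcodes were chosen after the results had been seen, as were the lists of tags present in 1 treatment. Among tags below the minimum for testing, 18 had 3 or more counts in both nanoparticle libraries and 0 in the other 6, of which 4 were error neighbours. For control there were 62 such tags (43 error neighbours), for silver ions 5 (2 error neighbours) and for bulk silver 0. Among tested tags, 26 had 0 counts in both silver ion libraries and 3 or more in each of the other 6, against 8 for nanoparticles, 1 for control and 0 for bulk silver.

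For the comparison of 48 with 24 hpf, the 8 libraries were split into 4 and 4 in all 35 ways, as if they were unpaired. Only the real split (1 of 35) gave as many calls, 1087, and the highest of the other splits gave 44. Both libraries of a treatment came from 1 chamber, so these splits ignore the pairing and do not exclude chance. The splits that swap times within treatments number 8, too few for a share under 0.05. Among these the real one gave 1087 calls and the highest other 0.

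A hypothesis was that the last base of each barcode had been read as part of the tag, which would raise length variants that begin with that base in the library that carries it. The mean effect over libraries was 0.081 for the real barcodes and as high as 0.128 for other assignments, and 5 of 24 assignments of the 4 bases to the 4 treatments gave as much, so this test leaves the hypothesis open.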
